A study of Mus musculus with 17 samples.

How the data were processed

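The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, as the file headers and the labels state, with 120951 barcodes over 17 libraries. Per the submitters' processing notes, reads were aligned to GRCm39 with Cell Ranger 8.0.1 after 10x 3′ version 3 chemistry. Per the file headers, 6 young or aged libraries came from Cell Ranger 8.0.0, 2 from 8.0.1 and all 9 treated libraries from 7.1.0, so treated and untreated libraries differ in version; the 2 from 8.0.1 are young 3 and 4, so version also differs between young and aged libraries in part. All libraries but young 3 and 4 list 32285 features, and those list 33696; 31950 are shared and only these were used. Shared features held 94.4–99.5% of the UMIs of a library, with 94.4–95.5% in aged and 97.8–99.5% in young libraries. The median mitochondrial share of UMIs was 1.42–1.96% in aged and 2.03–2.81% in young libraries. Neither range overlapped, so aged and young libraries also differed in these measures.

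Groups and replicate numbers follow the titles, and dates follow the labels. Young and aged libraries carry the same date, FL-RSV and ApoE-FL-RSV share another, and oral-RSV has its own. Liposomes were given at 2 mg/mL (0.117 mg/kg/day of resveratrol) and the oral form at 6 mg per mouse per day (200 mg/kg/day). The series text and the extraction protocol give different numbers per group, and nothing states that libraries are separate animals, so p-values measure spread between libraries.

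Barcodes were kept with at least 200 genes and at most 20% mitochondrial UMIs, which left 114975. Scrublet as run in scanpy 1.11.5 scored doublets per library with 30 components. Its automatic threshold marked too few cells in several libraries, so the highest scores were called at the expected rate of 0.8% per 1000 cells; 7857 doublets were removed and 107118 cells were kept. Counts were scaled to 10000 per cell and logged, 3000 variable genes and 40 principal components were taken, and cells were clustered over 20 neighbours with Leiden at resolution 1.5 (igraph 0.11.9, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, Python 3.11.15), without integration of dates. Figures used matplotlib 3.10.9.

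Clusters were named from fixed markers of 20 classes. A name needed at least 3 of its markers detected in 25% of cells. A cluster stayed unnamed when its top 10 genes held as many markers of another class, when another class had a mean marker detection of at least 0.5 and less than 0.25 below the first, or when it had low UMIs and no marker among its top 10 genes. Names are written as "-like" because they rest on RNA alone. Classes were compared only in libraries with at least 20 cells.

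Counts were summed per library and class and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM, estimateDisp, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment, threshold 0.05, each comparison fitted on its own libraries. Log2 fold changes carry the SE of the fit, and CPM carry the SD over libraries. Alternatives were RLE factors, DESeq2 1.42.0 (Wald test), no count filter, cells with at least 500 genes, called doublets kept, each cell thinned to 500 UMIs with shallower cells left out, the replicate number as a block, 1 fit of all libraries, the 2 young libraries of the longer feature list left out, and each library left out in turn. Thinning left out 178 young, 233 aged, 80 FL-RSV, 148 ApoE-FL-RSV and 8655 oral-RSV cells under 500 UMIs. A gene with 0 counts in a group is given a bound from a floor of 3 counts over the group, and one with 1–3 counts a ratio with a 95% interval.

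Lists with at least 3 measured genes were tested with limma 3.58.1 camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, with the estimated correlation beside it. The 24 fixed lists were tight and adherens junctions, barrier transporters, caveolae and transcytosis, angiogenesis, Wnt signalling, arterial and venous markers, leukocyte adhesion and NF-kB, interferon response, antigen presentation, senescence, NRF2 and antioxidant defence, sirtuins with AMPK and eNOS, oxidative phosphorylation, ribosomal proteins, basement membrane and integrins, immediate early and heat shock genes, lipoprotein receptors and cholesterol synthesis, unfolded protein response, disease-associated microglia, homeostatic microglia, reactive astrocytes, myelin and stressed oligodendrocytes. Markers of other cell classes were tested as lists as well.

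Named genes were those passing with mean log2 CPM of at least 5 and no overlap between libraries, up to 10 per direction (5 for other classes and for comparisons that coincide with date), up to 4 per list, and 14 key genes of endothelial-like cells. Of these, 3 genes are not reported here; they were dropped from the tables and counts of named genes after the choice, with no replacement, and 1 of them changed direction in an alternative. The text prints a part of them, mainly those whose call held in every alternative.

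Shares are percentages of kept cells per library, compared by exact permutation of the difference of means, two-sided, adjusted over 13 classes. The smallest exact p is 0.0286 for 4 against 4 and for 3 against 4 libraries, and 0.1 for 3 against 3. Ligand and receptor pairs (15 fixed) used the mean of log2(CPM+1) of both genes with the same test, with 0.1 and 10 CPM as other pseudocounts. Age and treatment effects were correlated across genes; shared aged libraries were handled by 20 simulations without effects and by using different aged libraries for each effect. Power was simulated with 1.5-, 2- and 4-fold changes in genes above a minimum mean expression.

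Replicate numbers were checked for pairing by correlating, across genes, the deviations from the group mean of libraries with the same number. For ApoE-FL-RSV and FL-RSV the values were 0.168, 0.127 and 0.226, and for pericyte-like cells of aged and young mice 0.148, 0.105, 0.120 and 0.173. All lie over 0.1, so these 2 comparisons were also run with the number as a block: 0 genes passed edgeR between ApoE-FL-RSV and FL-RSV (1030 unadjusted), and 1097 in pericyte-like cells.

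Groups, tests, lists, markers and most alternatives were fixed before the data were examined. The thresholds for naming clusters, the doublet rule, the wider endothelial class with 2 unnamed clusters, the fit without FL-RSV libraries that express Xist and every test of an explanation were chosen after the data had been seen.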

Results

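Cells were taken from mouse brains after perfusion, dissociation, debris removal and a sort for live cells, and were sequenced as 17 single-cell libraries. They formed 5 groups: young mice of 4–6 months (n = 4), aged mice of 18–20 months (n = 4), and aged mice given resveratrol for 1 month. The drug came in plain liposomes (FL-RSV, n = 3), in liposomes coated with apolipoprotein E (ApoE-FL-RSV, n = 3) or by mouth (oral-RSV, n = 3). The titles of the ApoE-FL-RSV and oral-RSV libraries call the mice very aged, although the same age range is given for them. After filtering, 107118 cells were kept: 38462 young, 30160 aged, 14491 FL-RSV, 9437 ApoE-FL-RSV and 14568 oral-RSV. Total UMIs per library were 36624167–54496379 in young, 26891336–50235043 in aged, 14211869–45230399 in FL-RSV, 5743734–24523123 in ApoE-FL-RSV and 2519359–3450849 in oral-RSV. Median UMIs per kept cell were 2379–4466, 2375–4689, 3356–7237, 897.5–5050 and 343–527 in the same order, so the oral-RSV libraries were much shallower than the rest.

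The first question was how brain endothelial-like cells, pericyte-like cells and glia of aged mice differed from those of young mice. A further question was whether the ApoE coating changed endothelial-like cells of FL-RSV mice, and whether any treatment moved genes against the direction of age. Young and aged libraries carried 1 batch date in the labels, and FL-RSV and ApoE-FL-RSV libraries shared another. Every comparison of a treated group with the aged group therefore coincided with a change of date, and its effect is not separable from that date. The authors aligned reads to GRCm39, and genes were matched between libraries by Ensembl identifier. All mice are labelled male, yet Xist, the RNA that silences an X chromosome in females, reached 967–1224 counts scaled to library size (CPM) in 5 treated libraries (FL-RSV 2 and 3, ApoE-FL-RSV 1 to 3). Its highest value in any young or aged library was 0.351 CPM.

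Endothelial-like cells, which form the wall of brain vessels, made up 40.4 ± 7.22% (mean ± SD) of cells in aged libraries and 15.3 ± 6.27% in young libraries (n = 4 each; exact permutation two-sided p = 0.0286, adjusted over 13 classes p = 0.0743). Astrocyte-like cells made up 0.227 ± 0.207% against 3.94 ± 1.75%, oligodendrocyte-like cells 0.318 ± 0.234% against 5.32 ± 3.56%, and neuroblast-like cells 0.0267 ± 0.0115% against 0.572 ± 0.233%. The values of the groups did not overlap for any of these 3 classes (each exact permutation p = 0.0286, adjusted p = 0.0743). Microglia-like cells were 22.9 ± 11.3% of aged and 47.4 ± 11.1% of young cells, and pericyte-like cells 12.98 ± 2.77% against 6.23 ± 3.91% (each exact permutation p = 0.0571, adjusted p = 0.106). Cluster 5, marked by Hmcn1, was the largest cluster of aged endothelial-like cells (47.5%), and cluster 22, marked by Apold1 and Cxcl12, the largest of young ones (31.0%). No share passed adjustment. Shares also follow the live-cell sort, debris removal and loss of fragile cells during dissociation, so they do not count cells in the tissue.

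**Figure D1:**
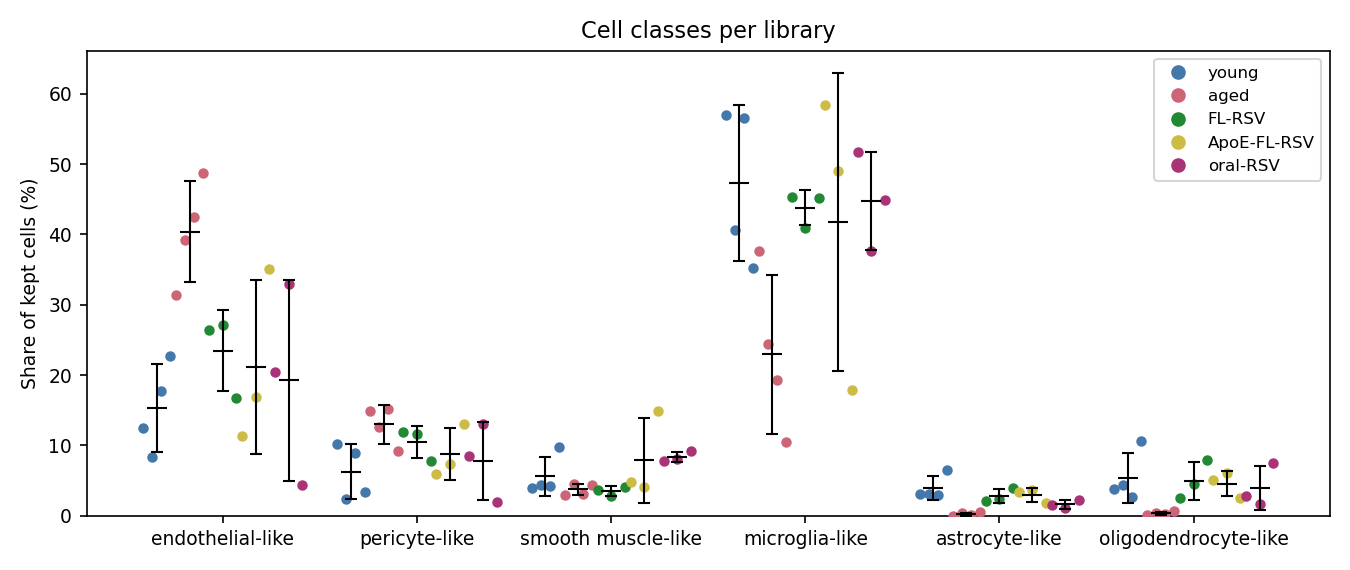
Share of kept cells in 6 named classes; each point is a library, colours are groups, and bars give the mean ± SD over libraries. Aged libraries held more endothelial-like cells and fewer astrocyte-like and oligodendrocyte-like cells than young libraries.

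In aged endothelial-like cells, transporter genes of the blood-brain barrier were among those that rose. Slc16a1, which carries lactate and ketone bodies, rose by 0.72 ± 0.08 log2 (mean ± SE; 524 ± 44.0 against 318 ± 26.3 CPM ± SD), and Tfrc, the transferrin receptor, rose by 0.61 ± 0.10 (832 ± 128 against 547 ± 35.9). The organic anion transporter Slco1a4 rose by 0.47 ± 0.08. All 3 are among the leading genes of cluster 5, which held 47.5% of aged and 10.7% of young endothelial-like cells, and their rise was not tested apart from this shift. Genes rising most included Cyp2e1, an oxidizing enzyme of xenobiotics (1.79 ± 0.18; 49.6 ± 8.49 against 14.8 ± 3.97 CPM), the heparan sulfate proteoglycan Gpc6 (1.74 ± 0.24) and Amy1, an amylase with near-identical copies (1.65 ± 0.15). Gpc6 is also a leading gene of pericyte-like cluster 29, and 6 of 8 pericyte markers rose in these cells. Its rise was not tested apart from RNA of pericytes. The small membrane polypeptide Spaar (1.19 ± 0.11) and the netrin Ntn4 (1.12 ± 0.12) rose as well. Each comparison in this paragraph had n = 4 against 4 and an edgeR adjusted p of at most 0.00174.

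Some collagen, junction and arterial genes fell with age. Basement membrane collagens Col4a1 and Col4a2 fell by 0.59 ± 0.06 and 0.67 ± 0.07 log2 (267 ± 10.7 against 404 ± 21.9 and 184 ± 15.9 against 293 ± 8.66 CPM), while the laminin chain Lama4 rose by 0.90 ± 0.08 (315 ± 24.5 against 168 ± 13.9). The tricellular junction gene Marveld2 fell by 1.47 ± 0.09 (13.6 ± 1.15 against 37.6 ± 3.20 CPM) and the junction adhesion molecule F11r by 0.49 ± 0.06. Sema3g, which marks arterial cells, fell to 13.5 ± 2.27 from 38.0 ± 2.80 CPM, Efnb2 fell by 0.73 ± 0.10 log2, and the Wnt receptor Fzd4 fell by 0.60 ± 0.07. With the unnamed arterial-like cluster 23 and cluster 33 added, Sema3g fell by 0.43 and Efnb2 by 0.46. Klf2, a transcription factor switched on by blood flow, fell by 0.88 ± 0.09 (443 ± 62.1 against 815 ± 38.3 CPM). Stress genes fell in the same cells, and the fall of Klf2 was not tested apart from theirs. Cldn5, the main tight junction claudin, fell by 0.33 ± 0.10 (edgeR adjusted p = 0.0243), but the call was lost without young library 2 (−0.22), aged library 1 (−0.29) or aged library 2 (−0.33). Ocln did not pass (−0.07 ± 0.06, edgeR adjusted p = 0.409), nor did the resveratrol-linked deacetylase Sirt1 (0.09 ± 0.08, adjusted p = 0.433). Nos3, which makes nitric oxide, fell by 0.21 ± 0.06 (edgeR adjusted p = 0.0274), a call lost without young libraries 1, 2 or 4 or aged libraries 2, 3 or 4 (−0.20, −0.17, −0.22, −0.21, −0.20 and −0.18). The adhesion molecule Vcam1 did not pass (0.78 ± 0.29, edgeR adjusted p = 0.0617) but did without aged library 1 (0.98) or 2 (0.93). Icam1, Mfsd2a, Vwf, Kdr, Plvap, Cdkn1a and Lrp1 did not pass edgeR (adjusted p from 0.174 to 0.961), though Mfsd2a did without aged library 3 (0.36) and Cdkn1a without young library 2 (−0.55).

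Stress genes that cells switch on within minutes fell with age. Jun fell by 2.86 ± 0.14 log2 (132 ± 17.3 against 960 ± 178 CPM), Fos by 2.55 ± 0.34, Atf3 by 3.01 ± 0.18, and the heat shock genes Hspa1b and Hspa1a, near-identical copies whose split is uncertain, by 6.49 ± 0.29 and 5.95 ± 0.34. Of 22 immediate early and heat shock genes, 1 rose and 21 fell, with 22 passing when adjusted over the list alone (camera adjusted p = 1.31e-17, adjusted p = 0.327 with an estimated correlation). These genes took 0.179–0.236% of endothelial UMIs in aged libraries and 0.481–0.615% in young libraries. Cluster 22 held 31.0% of young and 5.83% of aged endothelial-like cells, and the fall of stress genes was not tested apart from this shift.

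**Figure D2:**
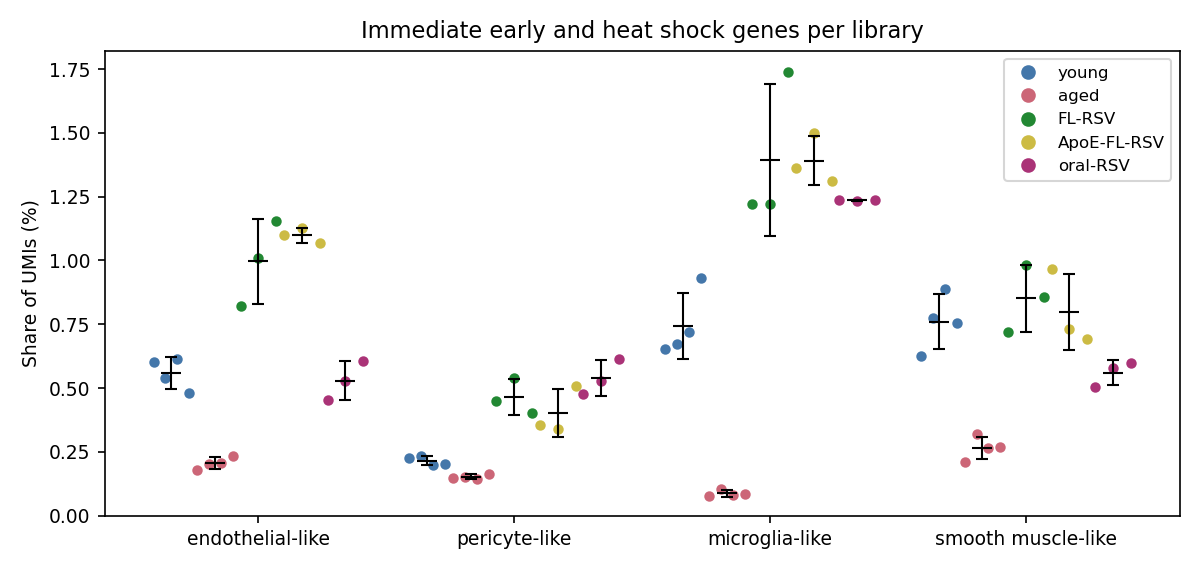
Share of UMIs from immediate early and heat shock genes in 4 classes; each point is a library, and bars give the mean ± SD. The aged libraries lie lowest in every class shown.

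Genes of other cell types moved together in aged endothelial-like cells. The myelin gene Mag fell by 3.59 ± 0.37 log2 (0.65 ± 0.399 against 8.15 ± 2.18 CPM), and the microglial genes Tyrobp and Gpr34 by 1.99 ± 0.44 and 1.69 ± 0.39. All 9 microglia markers fell (adjusted over the list alone 9; camera adjusted p = 0.00131, adjusted p = 0.530 with an estimated correlation), as did 7 of 8 oligodendrocyte markers (7 adjusted over the list alone; adjusted p = 0.000108, adjusted p = 0.478 with an estimated correlation). Of 12 myelin genes 10 fell and 2 did not pass (11 adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.478 with an estimated correlation), and of 12 homeostatic microglia genes 11 fell (12 over the list alone; adjusted p = 0.00134, adjusted p = 0.530 with an estimated correlation). Of 5 astrocyte markers 4 fell (4 over the list alone; camera adjusted p = 0.0134, adjusted p = 0.478 with an estimated correlation). Pericyte markers went the other way: 6 of 8 rose, among them Rgs5 by 1.32 ± 0.28 (6 over the list alone; adjusted p = 0.000821, adjusted p = 0.530 with an estimated correlation).

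Among the other lists that passed in these cells, 24 of 33 cytosolic ribosomal protein genes fell, 9 did not pass and 24 passed when adjusted over the list alone (camera adjusted p = 9.03e-07, adjusted p = 0.478 with an estimated correlation). Rps18 fell by 0.51 ± 0.09. In aged microglia-like cells 29 of 33 ribosomal and 11 of 13 unfolded protein response genes fell as well. In pericyte-like cells 0 of 33 and 0 of 13 passed. These falls were thus not particular to endothelial-like cells. Of 15 junction genes 1 rose, 6 fell and 8 did not pass (7 over the list alone; adjusted p = 0.00372, adjusted p = 0.478 with an estimated correlation). Of 22 genes of NRF2 and antioxidant defence 8 fell (10 over the list alone; camera adjusted p = 0.00243, adjusted p = 0.478 with an estimated correlation). Of 14 unfolded protein response genes 5 fell (5 over the list alone; camera adjusted p = 0.00743, adjusted p = 0.530 with an estimated correlation), and of 10 caveolar and transcytosis genes 4 fell (5 over the list alone; adjusted p = 0.0430, adjusted p = 0.478 with an estimated correlation).

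The remaining lists did not pass camera in aged against young endothelial-like cells. Of 21 barrier transporters 7 rose, 6 fell and 8 did not pass (13 over the list alone; adjusted p = 0.473), of 18 basement membrane and integrin genes 2 rose and 7 fell (9; adjusted p = 0.200), of 16 Wnt genes 3 rose and 5 fell (11; adjusted p = 0.224), and of 20 angiogenesis genes 2 rose and 6 fell (9; adjusted p = 0.168). The 24 interferon genes split 6 up and 1 down (7; camera adjusted p = 0.226), antigen presentation 3 up of 18 (3; adjusted p = 0.0822), senescence 4 down of 14 (6; adjusted p = 0.0822), and leukocyte adhesion 1 up and 1 down of 14 (0; adjusted p = 0.293). The group of sirtuins, AMPK and eNOS had 2 up and 7 down of 20 (9; camera adjusted p = 0.283), oxidative phosphorylation 1 down of 27 (0; adjusted p = 0.105), and lipoprotein receptors with cholesterol synthesis 3 down of 17 (3; adjusted p = 0.178). Arterial markers had 3 down of 10 (3; camera adjusted p = 0.254), venous markers 2 up of 8 (2; adjusted p = 0.501), disease-associated microglia genes 6 down of 12 (9; adjusted p = 0.0540), reactive astrocyte genes 3 up of 6 (4; adjusted p = 0.333) and stressed oligodendrocyte genes 1 up and 2 down of 7 (3; adjusted p = 0.501).

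In all, 3809 of 12914 tested genes passed edgeR in aged against young endothelial-like cells, 1836 up and 1973 down (two-sided, n = 4 against 4). Thinning every cell to 500 UMIs left 722, and leaving out both young libraries with the longer gene list left 2263. In simulations, which changed only genes above a minimum mean expression, 76.1% of genes with a 1.5-fold change were recovered.

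**Figure D3:**
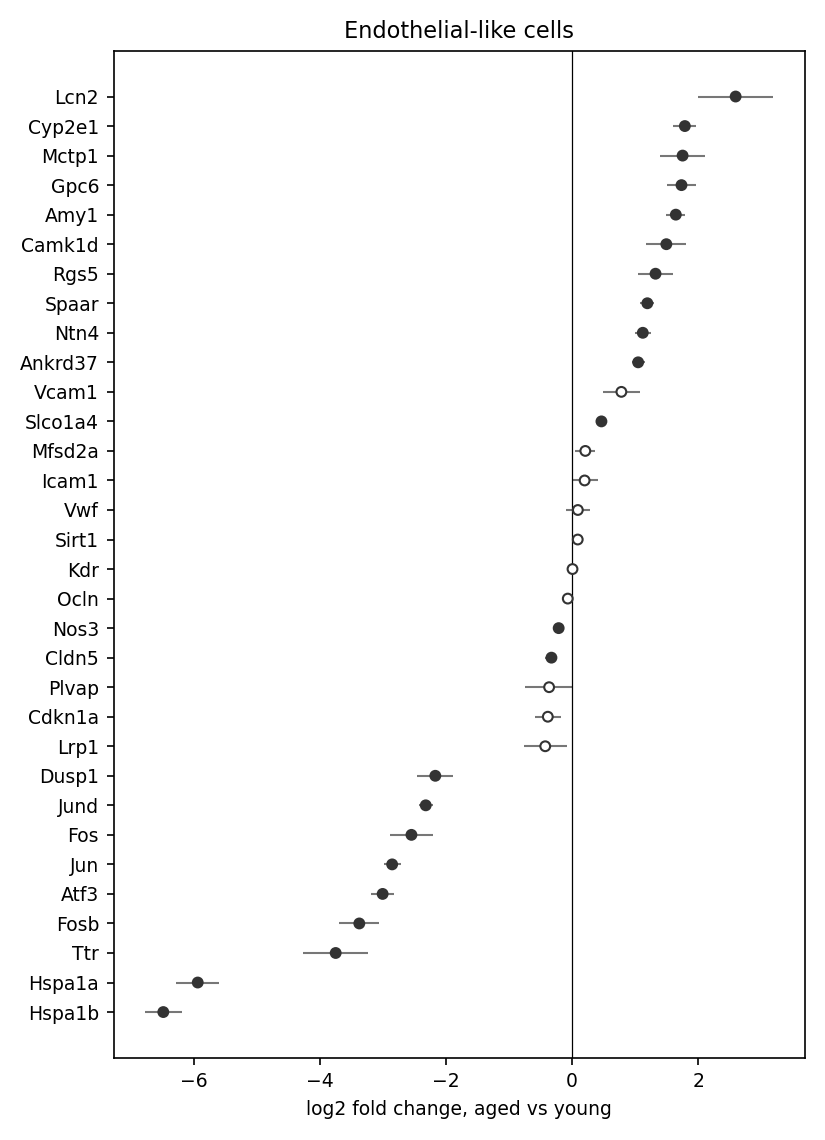
Log2 fold change of named genes in endothelial-like cells, aged against young (n = 4 each), with SE as bars; filled points passed edgeR and open points did not. Hspa1b and Hspa1a show the largest decreases among the genes drawn.

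In pericyte-like cells, which wrap the capillary wall, some matrix and cholesterol genes fell with age. The matrix protein gene Sparc fell by 0.44 ± 0.08 log2 (647 ± 62.0 against 879 ± 45.7 CPM), the protease inhibitor Timp2 by 1.41 ± 0.18 (11.3 ± 1.48 against 30.3 ± 5.18) and the cholesterol exporter Abca1 by 1.04 ± 0.16 (20.8 ± 3.43 against 44.8 ± 6.96). The axon guidance ligand Slit3 rose by 1.24 ± 0.17 (95.5 ± 20.8 against 39.2 ± 8.28) and the antiviral factor Zc3hav1 by 1.00 ± 0.14 (188 ± 39.0 against 91.5 ± 13.7). Of 17 genes for lipoprotein receptors and cholesterol synthesis 8 fell and 9 did not pass (12 adjusted over the list alone, camera adjusted p = 3.45e-07, adjusted p = 0.168 with an estimated correlation). All 9 microglia markers fell in these cells too. The falls of Sparc, Timp2, Abca1 and this list were not tested apart from RNA of microglia. Fos fell by 3.12 ± 0.21 and Hspa1a by 2.95 ± 0.20. Of 22 immediate early and heat shock genes 11 fell (16 over the list alone; camera adjusted p = 1.16e-10), the only list of the study that also passed with an estimated correlation (adjusted p = 0.0408).

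Microglial and myelin genes moved in pericyte-like cells as they did in endothelial-like cells. Tyrobp fell by 2.67 ± 0.39 log2 and Trem2 by 2.31 ± 0.39, and all 9 microglia markers fell (9 adjusted over the list alone; camera adjusted p = 5.61e-11, adjusted p = 0.170 with an estimated correlation). Of 9 myelin genes 7 fell (8 over the list alone; camera adjusted p = 3.39e-06, adjusted p = 0.168 with an estimated correlation). Interferon genes passed upward with 2 of 22 rising (3 over the list alone; adjusted p = 0.00110, adjusted p = 0.168 with an estimated correlation), as did oxidative phosphorylation with 3 of 27 rising (6; camera adjusted p = 9.72e-05, adjusted p = 0.491 with an estimated correlation). In all 936 of 11698 genes passed edgeR, 303 up and 633 down (two-sided, n = 4 against 4), and 10 of 32 lists passed camera. The count was 559 without young library 3, 604 without aged library 2, 618 without aged library 3, 372 without both young libraries of the longer gene list and 265 after thinning.

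Apoe and Lpl were among the genes that rose in aged microglia-like cells. Apoe, the main lipid carrier of the brain, rose by 2.28 ± 0.26 log2 (938 ± 395 against 194 ± 43.0 CPM), the lipoprotein lipase Lpl by 2.94 ± 0.29 (73.6 ± 32.7 against 9.86 ± 3.18), the phagocytic receptor Axl by 1.79 ± 0.15 (18.9 ± 1.28 against 5.48 ± 1.01) and Spp1, an osteopontin of reactive microglia, by 5.52 ± 0.73 (82.3 ± 88.0 against 1.83 ± 0.614). Apoe, Lpl and Spp1 lead cluster 15, which held 1.04% of aged and 0.313% of young microglia-like cells, and Apoe is a leading gene of cluster 34 (3.53% and 0.472%); their rise was not tested apart from these shifts. Genes of resting microglia fell: Tmem119 by 0.59 ± 0.07 (438 ± 39.4 against 660 ± 35.6) and the fractalkine receptor Cx3cr1 by 0.47 ± 0.08. Of 16 disease-associated microglia genes 7 rose and 3 fell (11 adjusted over the list alone; camera adjusted p = 0.0467, adjusted p = 0.613 with an estimated correlation), and of 12 homeostatic genes 1 rose and 8 fell (11; adjusted p = 2.23e-05, adjusted p = 0.338 with an estimated correlation). Of 23 interferon genes 13 rose and 1 fell (18; camera adjusted p = 2.95e-06, adjusted p = 0.338 with an estimated correlation), among them Rtp4 by 1.01 ± 0.17. Endothelial markers rose in these cells as well (9 of 10). The rises of Axl and of interferon genes were not tested apart from RNA of vessel cells. Cluster 9 held most aged microglia-like cells (53.2%) and cluster 10, marked by P2ry12, was the largest cluster of young ones (47.4%, against 30.8% of aged ones). The clusters differed in depth: median UMIs were 1580 in cluster 9 (0.497 times the level of its libraries) and 4798 in cluster 10 (1.45 times). Tmem119 and Cx3cr1 are among the leading genes of cluster 10, and their fall was not tested apart from this shift or this depth.

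Stress and inflammatory genes fell in the same cells. Fos fell by 7.60 ± 0.38 log2 (2.08 ± 1.44 against 332 ± 121 CPM), Klf2 by 4.52 ± 0.32, the chemokine Ccl2 by 3.76 ± 0.60 (3.66 ± 3.46 against 46.5 ± 28.4), and the NF-kB inhibitor Nfkbia by 1.95 ± 0.15 (65.4 ± 11.3 against 248 ± 44.4). Hspa1a had 3 counts in aged cells, a ratio of 807 (95% counting interval 276–3916). Cluster 14, with Atf3 and chemokine genes among its leading genes, held 19.1% of young and 0.0735% of aged microglia-like cells, and the fall of stress and inflammatory genes was not tested apart from this shift. Of 22 immediate early and heat shock genes 20 fell (21 adjusted over the list alone; camera adjusted p = 3.24e-22, adjusted p = 0.282 with an estimated correlation), and of 14 leukocyte adhesion and NF-kB genes 1 rose and 8 fell (10; adjusted p = 0.000593, adjusted p = 0.282 with an estimated correlation). Of 33 ribosomal protein genes 29 fell (31; camera adjusted p = 2.31e-13, adjusted p = 0.338 with an estimated correlation), and of 13 unfolded protein response genes 11 fell (11; adjusted p = 7.1e-07, adjusted p = 0.338 with an estimated correlation). Endothelial genes rose in these cells, with Flt1 up by 1.85 ± 0.23 and 9 of 10 endothelial markers rising (9; camera adjusted p = 1.16e-06, adjusted p = 0.338 with an estimated correlation), while 6 of 8 oligodendrocyte markers fell and 1 rose (8; adjusted p = 0.000963, adjusted p = 0.338 with an estimated correlation).

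In microglia-like cells 3347 of 13747 genes passed edgeR, 1590 up and 1757 down (two-sided, n = 4 against 4), and 17 of 34 lists passed camera. Thinning left 1287 genes, and leaving out both young libraries with the longer gene list left 1888.

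**Figure D4:**
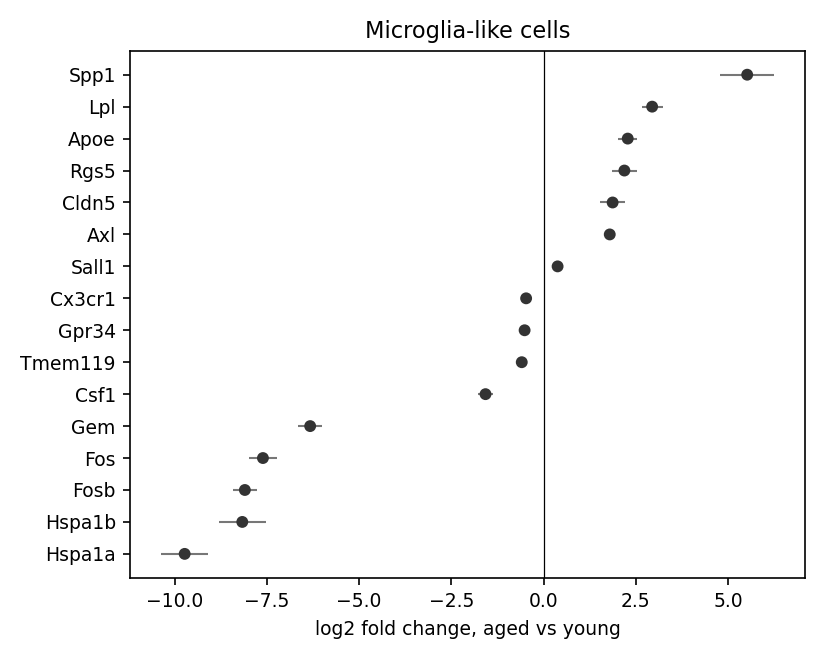
Log2 fold change of named genes in microglia-like cells, aged against young (n = 4 each), with SE as bars; all points shown passed edgeR. Spp1, Lpl and Apoe lie highest and heat shock genes lowest.

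Oligodendrocyte-like cells reached 20 cells in only 2 aged libraries (22 and 53 cells). The kinase gene Camk1d rose by 2.84 ± 0.23 log2 and the cadherin Cdh8 by 2.72 ± 0.23 (411 ± 108, n = 2, against 56.8 ± 9.67 CPM, n = 4). The myelin genes Cnp (−1.13 ± 0.15) and Mal (−1.16 ± 0.18) fell, and both calls were lost without aged library 4 (−0.94 and −0.87). Of 12 myelin genes 3 fell and 9 did not pass (10 adjusted over the list alone; camera adjusted p = 2.69e-10, adjusted p = 0.113 with an estimated correlation). Of 9 endothelial markers 8 rose (9; camera adjusted p = 1.28e-16, adjusted p = 0.215 with an estimated correlation). The endothelial genes Tek, Eng and Slco1c1 had 0 CPM in the aged library of 22 cells and 83.5, 71.0 and 150 CPM in aged library 4, so their rise rests on the latter alone. Fos had 1 aged count, a ratio of 40.4 (95% counting interval 7.24–1596), and Egr1 had 0, at least 5.31-fold lower. In all 207 of 10600 genes passed edgeR, 110 up and 97 down, and 16 of 30 lists passed camera; the gene count was 8 without aged library 4 (a single aged library, assumed to vary like the young ones), 125 without young library 1, 101 without young library 2 and 18 after thinning.

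Astrocyte-like cells reached 20 cells in 1 aged library (40 cells), so this class has no aged spread and no gene or list of it is called. Endothelial transcripts were high in that library: Flt1 stood at 417 CPM against 21.9 ± 10.5 in young libraries (n = 4), Cldn5 at 284 against 16.5 ± 10.5 and Tek at 101 against 3.75 ± 2.16. Fits that assume the lone library to vary like the young ones gave 24 of 11837 genes by edgeR, 45 by DESeq2 and without young library 4, 5 with called doublets kept, 1 after thinning, 120 without the young libraries of the longer gene list and 126 with no filter on low counts.

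No gene passed edgeR between ApoE-FL-RSV and FL-RSV endothelial-like cells. FL-RSV library 1 expressed the Y chromosome gene Uty (125 CPM) and almost no Xist (0.105 CPM). The other FL-RSV libraries and all ApoE-FL-RSV libraries expressed Xist. Titles of the ApoE-FL-RSV libraries also call the mice very aged, so this comparison does not isolate the coating. Cldn5 was 3359 ± 254 CPM in ApoE-FL-RSV and 3687 ± 111 in FL-RSV (n = 3 each; −0.13 ± 0.11 log2, edgeR adjusted p = 0.880), Ocln differed by −0.16 ± 0.11 (adjusted p = 0.856) and Slco1a4 by −0.13 ± 0.12 (adjusted p = 0.902). The growth factor receptor Kdr differed by 0.15 ± 0.10 (edgeR adjusted p = 0.856), Icam1 by 0.30 ± 0.24 (adjusted p = 0.878), Nos3 by −0.09 ± 0.09 (adjusted p = 0.911) and the adhesion molecule Vcam1 by 0.57 ± 0.33 (509 ± 188 against 343 ± 168 CPM, adjusted p = 0.848). Sirt1 differed by −0.14 ± 0.17 (edgeR adjusted p = 0.928), and by 0.05 without FL-RSV library 2. Mfsd2a, Vwf, Cdkn1a and Lrp1 did not pass edgeR (adjusted p from 0.863 to 0.990), and Plvap had too few counts to test.

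Of 11051 genes 0 passed edgeR (two-sided, n = 3 against 3), while 619 had an unadjusted p under 0.05. DESeq2 called 7 (246 unadjusted) and edgeR with no filter on low counts called 155, Vcam1 among them; leaving out FL-RSV library 3 gave 45 and FL-RSV library 1 gave 1. In simulations 58.2% of 2-fold and 98.5% of 4-fold changes were recovered, so changes under 4-fold were often out of reach. Only genes above a minimum mean expression were changed in the simulations, so recovery of weaker genes is not known. By camera 11 of 32 lists passed, with no single gene in them passing edgeR. Of 33 ribosomal protein genes 6 passed when adjusted over the list alone (upward; camera adjusted p = 4.02e-09), of 14 leukocyte adhesion genes 1 (upward; adjusted p = 7.08e-05) and of 27 oxidative phosphorylation genes 1 (upward; adjusted p = 6.71e-05). Lists in which 0 genes passed over the list alone were markers of microglia (downward, median −1.08 log2; camera adjusted p = 0.0118) and homeostatic microglia genes (downward; 0.0110), and, all upward, markers of astrocytes (0.0335), reactive astrocyte genes (0.0272), markers of erythroid cells (0.0341), interferon (0.00311), stress (0.0131) and venous genes (0.0185). All 11 had adjusted p = 0.751 with an estimated correlation, and genes of other cell types were thus among those that differed by list. Endothelial-like cells were 21.1 ± 12.4% of ApoE-FL-RSV and 23.5 ± 5.78% of FL-RSV cells (exact permutation two-sided p = 0.9, adjusted p = 1); without ApoE-FL-RSV library 1 the difference was 2.53 points.

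In FL-RSV endothelial-like cells, Klf2, Klf4 and some transporter genes differed from the aged group. Klf2 rose by 1.75 ± 0.13 log2 and Klf4, its partner in the response to flow, by 1.53 ± 0.14 (798 ± 80.8, n = 3, against 277 ± 54.4 CPM, n = 4). Stress genes rose in the same cells, and the rises of Klf2 and Klf4 were not tested apart from theirs. The glucose transporter Slc2a1 rose by 0.48 ± 0.09 and the Wnt receptor Fzd4 by 0.90 ± 0.12 (139 ± 27.5 against 74.8 ± 5.00). Tfrc fell by 1.00 ± 0.13 (410 ± 34.3 against 823 ± 126), Slc16a1 by 0.77 ± 0.11 (304 ± 41.4 against 518 ± 42.4), Lama4 by 0.91 ± 0.12 and Amy1 by 1.73 ± 0.14. The cell-cycle inhibitor Cdkn1a rose by 1.51 ± 0.20 (278 ± 96.8 against 97.4 ± 14.7 CPM), and Jun rose by 3.88 ± 0.15. Cluster 5, with Tfrc and Slc16a1 among its leading genes, held 6.37% of FL-RSV and 47.5% of aged endothelial-like cells, and cluster 22, with Cdkn1a, 39.5% and 5.83%; the changes of these genes were not tested apart from this shift. Icam1 rose by 1.55 ± 0.30. With the single FL-RSV library without Xist, assumed to vary like the aged libraries, it was 0.94 and did not pass. Cldn5 rose by 0.35 ± 0.10 (edgeR adjusted p = 0.0268), a call lost without aged libraries 1, 2 or 3 or FL-RSV library 1 (0.31, 0.36, 0.35 and 0.37). Sirt1 did not pass (0.17 ± 0.13, edgeR adjusted p = 0.346; −0.02 without FL-RSV library 2), nor did Vcam1, Kdr, Mfsd2a, Nos3 or Lrp1.

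All 22 immediate early and heat shock genes rose in FL-RSV cells (22 adjusted over the list alone; camera adjusted p = 1.94e-23, adjusted p = 0.354 with an estimated correlation), as did 32 of 33 ribosomal protein genes (32; adjusted p = 1.82e-15, adjusted p = 0.354 with an estimated correlation). Of 27 oxidative phosphorylation genes 22 rose (23; camera adjusted p = 5.57e-11, adjusted p = 0.354 with an estimated correlation) and of 14 senescence genes 7 rose and 1 fell (8; adjusted p = 0.00681, adjusted p = 0.354 with an estimated correlation). Of 7 myelin genes 5 rose (5; camera adjusted p = 0.0224, adjusted p = 0.354 with an estimated correlation). Barrier transporters did not pass (3 up, 7 down of 21; camera adjusted p = 0.110), nor did junction genes (2 up, 3 down of 15; adjusted p = 0.808). In all 3621 of 13669 genes passed edgeR, 1813 up and 1808 down (two-sided, n = 3 against 4), and 14 of 35 lists passed. Thinning left 772 genes, and the single FL-RSV library without Xist gave 1808.

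In ApoE-FL-RSV endothelial-like cells, some adhesion genes rose and some transporter genes fell against aged cells. The leukocyte receptors Icam1 and Icam2 rose by 1.86 ± 0.20 log2 (186 ± 11.3, n = 3, against 50.8 ± 16.5 CPM, n = 4) and 0.67 ± 0.08 (182 ± 2.68 against 114 ± 9.57), and Vwf, the clotting factor of larger vessels, by 1.08 ± 0.19 (808 ± 114 against 380 ± 106). The junction cadherin Cdh5 rose by 0.43 ± 0.09 (523 ± 9.40 against 389 ± 41.4) and the caveolar gene Cavin2 by 0.57 ± 0.08. Slc16a1 fell by 1.00 ± 0.12 (253 ± 53.4 against 514 ± 41.8), Slco1a4 by 0.60 ± 0.11 and Tfrc by 0.90 ± 0.14. The last 3 are among the leading genes of cluster 5, which held 7.06% of ApoE-FL-RSV and 47.5% of aged endothelial-like cells, and Vwf of the venous cluster 3, which held 26.3% and 10.6%; the changes of these genes and of venous markers were not tested apart from this shift. Cldn5 did not pass by edgeR (0.23 ± 0.10, adjusted p = 0.101), though DESeq2 and the replicate block called it (0.23 and 0.27). Sirt1, Nos3, Kdr, Mfsd2a, Plvap and Lrp1 did not pass edgeR (adjusted p from 0.364 to 0.894). Uty, a Y chromosome gene, had 0 counts, at least 319-fold lower than in aged cells.

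Of 15 leukocyte adhesion and NF-kB genes 8 rose and 1 fell (14 adjusted over the list alone; camera adjusted p = 0.000442, adjusted p = 0.395 with an estimated correlation), and of 9 venous markers 6 rose (7; adjusted p = 0.000453, adjusted p = 0.391 with an estimated correlation). All 22 stress genes rose (22; camera adjusted p = 8.14e-28, adjusted p = 0.0604 with an estimated correlation), with Jun up by 4.08 ± 0.11 log2, as did 33 of 33 ribosomal protein genes (33; adjusted p = 2.94e-27, adjusted p = 0.209 with an estimated correlation). Of 10 caveolar and transcytosis genes 5 rose (6; camera adjusted p = 0.0285, adjusted p = 0.209 with an estimated correlation). Of 21 barrier transporters 3 rose and 9 fell (12; camera adjusted p = 0.0657). In all 4221 of 13224 genes passed edgeR, 2163 up and 2058 down (two-sided, n = 3 against 4), and 16 of 33 lists passed; thinning left 869 genes.

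In oral-RSV endothelial-like cells some transporter genes fell against aged cells, and arterial genes rose in a way that depended on which clusters were counted. Mgp, a calcification inhibitor of large vessels, rose by 3.25 ± 0.21 log2 (474 ± 84.0, n = 3, against 47.0 ± 14.5 CPM, n = 4), the cytokine-like gene Cytl1 by 5.05 ± 0.43 and the elastic fibre gene Fbln5 by 4.74 ± 0.51. Vwf rose by 0.94 ± 0.20 (773 ± 134 against 396 ± 110) and the antigen-presenting gene H2-K1 by 1.06 ± 0.18 (978 ± 265 against 494 ± 129). Slco1a4 fell by 0.82 ± 0.16, the thyroid hormone transporter Slco1c1 by 1.05 ± 0.15, Slc16a1 by 1.17 ± 0.15 (207 ± 84.0 against 536 ± 43.2) and Tfrc fell to 346 ± 86.8 from 851 ± 130 CPM. Sirt1 fell by 0.52 ± 0.17 (edgeR adjusted p = 0.0363), a call lost without aged libraries 1, 2 or 3 (−0.49, −0.46, −0.50) or oral-RSV libraries 1 or 2 (−0.58, −0.53). Cluster 6, a cluster of few UMIs (median 498) marked by Pglyrp1 and Bsg, held 72.2% of the oral-RSV endothelial-like cells, and cluster 5, with Slco1a4, Slco1c1, Slc16a1 and Tfrc among its leading genes, held 1.65% of them and 47.5% of aged ones; the falls of these genes were not tested apart from this shift. Nor was the rise of Vwf, a leading gene of cluster 3, which held 19.0% of oral-RSV and 10.6% of aged endothelial-like cells.

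Of 12 arterial markers 10 rose in oral-RSV cells (10 adjusted over the list alone; camera adjusted p = 6.19e-08, adjusted p = 0.0569 with an estimated correlation), a call lost with clusters 23 and 33 added (camera adjusted p = 0.650). Of 21 barrier transporters 3 rose and 9 fell (15; adjusted p = 0.00355, adjusted p = 0.572 with an estimated correlation). Ribosomal protein genes rose in 32 of 33 cases (32; camera adjusted p = 2.46e-28, adjusted p = 0.138 with an estimated correlation), oxidative phosphorylation genes in 24 of 27 (25; adjusted p = 4.85e-16, adjusted p = 0.266 with an estimated correlation) and stress genes in 18 of 22 (19; adjusted p = 2.58e-13, adjusted p = 0.138 with an estimated correlation). Smooth muscle markers rose in 4 of 5 cases (camera adjusted p = 0.00819, adjusted p = 0.504 with an estimated correlation), and smooth-muscle-like cells were 8.34 ± 0.735% of oral-RSV against 3.75 ± 0.807% of aged cells (exact permutation two-sided p = 0.0286, adjusted p = 0.0619). In all 3459 of 13185 genes passed edgeR, 1669 up and 1790 down (two-sided, n = 3 against 4), and 14 of 33 lists passed. The gene count was 2203 without oral-RSV library 1, 1797 without oral-RSV library 2, 2210 in cells with at least 500 genes and 1304 after thinning.

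Unnamed clusters led by endothelial genes were kept out of these values. Cluster 23, with the arterial genes Bmx, Vegfc, Gkn3 and Sema3g, was 1.67% of young, 11.2% of aged, 2.78% of FL-RSV, 1.05% of ApoE-FL-RSV and 0.248% of oral-RSV cells. Cluster 33, with Plvap and Esm1, was 1.21, 1.81, 1.08, 1.49 and 1.32% in that order. Cluster 20, with Gkn3, Vegfc, Bmx and the pericyte gene Rgs5 and with UMIs at 2.51 times the level of its libraries, was 1.98% of aged and 0.0690% of oral-RSV cells and was not added. Most oral-RSV endothelial-like cells (72.2%) lay in cluster 6, of few UMIs, so oral-RSV shares of these clusters may not be comparable. With clusters 23 and 33 added, Gkn3 fell short (0.39 against 3.20 log2) in oral-RSV against aged cells, and Mgp, Cytl1 and Fbln5 rose by only 1.65, 1.84 and 1.80 log2. The arterial list call and the size of these rises therefore depend on whether these clusters are counted. Endothelial-like cells were 16.95, 19.3 and 21.1 points fewer in FL-RSV, ApoE-FL-RSV and oral-RSV than in aged libraries (exact permutation two-sided p = 0.0571, 0.0857 and 0.0857), and none passed adjustment. For oral-RSV against aged the difference was −13.7 points without oral-RSV library 3 and −28.0 points without library 2.

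Genes that differed with age tended to differ the opposite way with treatment. Slc16a1, Tfrc and Amy1 rose with age and fell in FL-RSV and ApoE-FL-RSV cells, and Klf2 and Jun fell with age and rose in all 3 treated groups. Across 12872 genes the correlation of age and FL-RSV effects was −0.692 (Spearman −0.636, covariance −0.172, 74.1% of genes opposite). It was −0.519 for ApoE-FL-RSV (12820 genes, Spearman −0.517, covariance −0.148, 70.0% opposite) and −0.361 for oral-RSV (12795 genes, Spearman −0.463, covariance −0.181, 69.0% opposite). Both effects use the aged libraries, and simulations without any effect gave −0.368, −0.299 and −0.157 with Spearman −0.339, −0.279 and −0.191, covariances −0.0182, −0.0160 and −0.0184 and 62.4, 60.2 and 57.3% of genes opposite. With aged libraries split so that none was shared, correlations were −0.573 to −0.641 for FL-RSV, −0.418 to −0.539 for ApoE-FL-RSV and −0.401 to −0.530 for oral-RSV. Each treated group differs from the aged group in date as well as in drug, so the opposite movement is not separable into these. Cluster 5 held 47.5% of aged endothelial-like cells against 10.7% of young, 6.37% of FL-RSV, 7.06% of ApoE-FL-RSV and 1.65% of oral-RSV ones. Cluster 22 held 5.83% of aged ones against 31.0, 39.5, 28.75 and 1.65% in that order. The opposite movement was not tested apart from this shift.

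**Figure D5:**
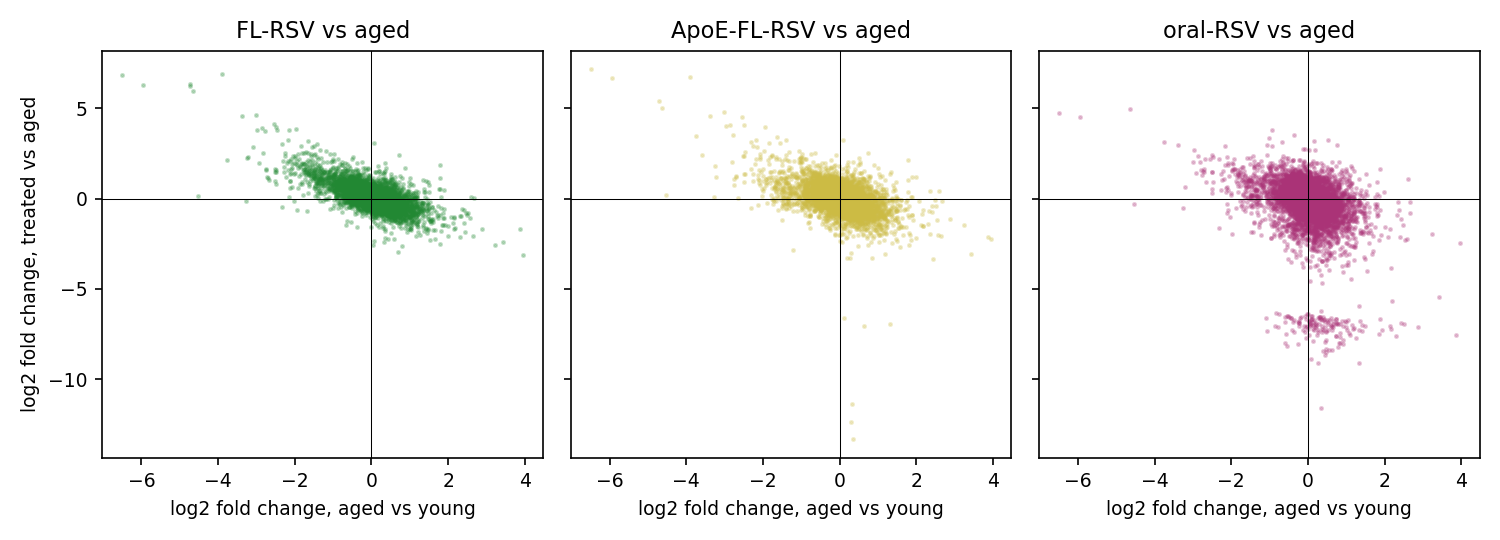
Log2 fold change with age against log2 fold change with treatment for each gene in endothelial-like cells, 1 panel per treatment. Points lie mostly in the quadrants of opposite sign, and the separate low cloud of the oral-RSV panel holds nearly only genes with 0 counts there.

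Within single dates, the age effect and the difference between ApoE-FL-RSV and FL-RSV showed a correlation of 0.147 across 11030 genes (Spearman 0.0561, covariance 0.0161). The 10 ways of grouping the liposome libraries gave 0.0556–0.175, the real one included. All 10 keep FL-RSV library 1 in the FL-RSV arm, and swapping the arms would reverse the sign. This range therefore does not give the spread of chance values around 0. Signalling between vessel cells was compared as the mean log2(CPM+1) of ligand and receptor in 11 measurable pairs. Angpt1 from pericyte-like cells with its endothelial receptor Tek was lower in aged libraries by 0.51, Dll4 with Notch1 by 0.41, Jag1 with Notch3 by 0.23 and Tgfb1 with Tgfbr2 by 0.20 (n = 4 each). Tnf from microglia-like cells with Tnfrsf1a was lower by 2.06. Each of these 5 had an exact permutation two-sided p = 0.0286 (adjusted p = 0.0629), so no pair passed. Between ApoE-FL-RSV and FL-RSV 15 pairs were compared, the smallest exact permutation p was 0.1 (Cxcl12 with Cxcr4, difference 0.41, adjusted p = 0.625), and none passed.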

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

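The values of Xist and of the pituitary cluster were sought only after the data had been seen, while the search for single libraries far from their group was planned. That search compared each library with the other 3 of its group in 104 groups and marked 14 values, all within 5 libraries; chance alone marks about 1 in 20 groups.

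Astrocyte-like cells were 6.56% of young library 4 against 2.96–3.15% in the other young libraries. Smooth-muscle-like cells were 9.70% of the same library (others 4.00–4.32%), and neutrophil-like cells 0.884% (others 0.201–0.240%). In young library 2 unnamed cells were 33.1% (others 3.23–5.27%), of which cluster 31, with haemoglobin and smooth muscle genes, made up 30.8%. Choroid plexus-like cells were 0.281% of aged library 2 (others 0–0.0473%). Stress genes took 0.0783% of astrocyte UMIs in young library 3 (others 0.0662–0.0670%).

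Among endothelial genes, the neutrophil-linked lipocalin Lcn2 reached 151 CPM in aged library 4 (others 24.8–40.4), and Spaar 57.5 CPM (others 43.0–45.5). Hspa1a was 11.03 CPM in aged library 2 (others 2.52–3.43), and Jun 158 CPM (others 123–125). Cldn5 was 4511 CPM in young library 2 (others 3424–3606), and Plvap 0.687 CPM (others 1.73–1.84). Camk1d was 2105 CPM in young library 3 (others 1406–1452), and Ocln 342 CPM (others 377–380).

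Xist was 1124 CPM in FL-RSV library 2 and 1224 in library 3, and 1137, 1136 and 967 CPM in ApoE-FL-RSV libraries 1, 2 and 3, against at most 0.351 CPM in young and aged libraries; the labels give male mice throughout. Cells led by the pituitary hormone genes Gh, Prl and Pomc were 22.4% of oral-RSV library 3, against at most 0.171% in any young or aged library.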

How the results depend on the processing

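The wider endothelial class and the fit without FL-RSV libraries that express Xist were chosen after the data had been seen; all other alternatives were planned. Treated groups differ from aged mice in date, software version, depth and, in 5 libraries, expressed sex genes, so no treated comparison isolates the drug. FL-RSV library 1 lacks the Xist of the other liposome libraries, so ApoE-FL-RSV against FL-RSV does not isolate the coating either. Names of cells rest on markers, groups hold 3 or 4 libraries, and no cause of a change listed here was tested unless stated. Where a group holds 1 library (aged astrocyte-like cells, oligodendrocyte-like cells without an aged library, FL-RSV without its libraries with Xist), that library is assumed to vary like the other group.

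With clusters 23 and 33 added, the endothelial difference was 35.3 points for aged against young (exact permutation p = 0.0286, adjusted p = 0.0743), and −26.1, −29.8 and −32.6 points for FL-RSV, ApoE-FL-RSV and oral-RSV against aged (exact permutation p = 0.0571, 0.0286 and 0.0286; adjusted p = 0.106, 0.0531 and 0.0531). Leaving out 1 library moved ApoE-FL-RSV against FL-RSV from −9.30 to 2.53 points.

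Thinning to 500 UMIs, which removes counts by construction, left 722 genes for aged against young endothelial-like cells, 772, 869 and 1304 for FL-RSV, ApoE-FL-RSV and oral-RSV against aged, 265 in pericyte-like, 1287 in microglia-like, 1 in astrocyte-like and 18 in oligodendrocyte-like cells. Without the young libraries of the longer feature list, edgeR called 2263 in endothelial-like, 372 in pericyte-like, 1888 in microglia-like and 120 in astrocyte-like cells. FL-RSV without its libraries with Xist gave 1808, and oral-RSV in cells with at least 500 genes gave 2210. For ApoE-FL-RSV against FL-RSV DESeq2 called 7 and no count filter 155. Without a count filter 1406 passed in pericyte-like, 126 in astrocyte-like and 710 in oligodendrocyte-like cells; with called doublets kept 1445 passed in pericyte-like and 5 in astrocyte-like cells, and DESeq2 called 45 in the latter. Leaving out 1 library gave 0–45 for ApoE-FL-RSV against FL-RSV, 1797–3418 for oral-RSV, 559–865 in pericyte-like, 21–45 in astrocyte-like and 8–293 in oligodendrocyte-like cells.

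With the estimated correlation 0 lists passed in any comparison except pericyte-like cells, where 1 did. Leaving out 1 library gave 6–14 lists for ApoE-FL-RSV against FL-RSV.

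Some genes changed direction. With the wider class Alpl was 0.0913 log2 for aged against young and Nrp1 0.19 for ApoE-FL-RSV against aged. Thinning gave −0.24 for Cd63 in oral-RSV and −0.46 for Sparcl1 in oligodendrocyte-like cells. Without aged library 4 the oligodendrocyte-like cells rested on 22 aged cells with 0 counts of some endothelial genes, so their negative values sit at the floor and show no reversal: leaving out 1 aged library gave −7.19 to 4.08 for Slco1c1, −6.16 to 4.04 for Eng, −6.52 to 4.09 for Lef1, −6.74 to 3.45 for Itga1 and −6.10 to 4.32 for Tek.

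The correlation of age and treatment effects was −0.821 for FL-RSV, −0.655 for ApoE-FL-RSV and −0.596 for oral-RSV when only genes passing with age were used, and −0.411 for ApoE-FL-RSV after thinning. Leaving out 1 treated library gave −0.709 to −0.545, −0.515 to −0.458 and −0.311 to −0.257. With different aged libraries for age and treatment it was −0.582 (2 and 3 for age) and −0.573 (3 and 4) for FL-RSV, and −0.432 (2 and 3), −0.449 (2 and 4) and −0.418 (3 and 4) for ApoE-FL-RSV. For oral-RSV it was −0.530 (1 and 2), −0.427 (1 and 3), −0.497 (1 and 4), −0.427 (2 and 3), −0.468 (2 and 4) and −0.401 (3 and 4).

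Pairing by replicate number was also checked in the other comparisons. Same-numbered deviations correlated at 0.192, 0.113, −0.106 and 0.255 in endothelial-like cells of aged and young mice, and at 0.300, −0.0723 and 0.165 (FL-RSV), 0.110, −0.0175 and 0.0981 (ApoE-FL-RSV) and −0.00607, 0.0663 and 0.0205 (oral-RSV) against aged. Microglia-like cells gave 0.0912, 0.103, 0.0350 and 0.0236, and oligodendrocyte-like cells 0.119 and 0.149, where the block left 125 genes; the block changed no other call on these counts beyond 1.5-fold.

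Over all alternatives, counts of genes, lists and pairs and correlations of effects stayed in 226 and moved in 68, and endothelial shares stayed in 55 and moved in 5. Genes stayed in 8634, weakened in 657, strengthened in 22, moved in 45 and turned in 9; lists stayed in 2366, weakened in 211, strengthened in 125 and moved in 145. Pairs stayed in 221 and moved in 9, and other shares stayed in 607 and moved in 53.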

Other observations

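All tests of explanations in this part, and the regroupings of libraries, were written after the results were seen. Resident macrophages at the brain border showed the widest gap of stress genes: these took 0.0945–0.211% of UMIs in aged libraries and 1.62–2.39% in young libraries (n = 4 each), while in smooth-muscle-like cells the values were 0.212–0.319% and 0.624–0.889%. Microglia-like cells of cluster 14, with Cd83, Atf3 and the chemokine genes Ccl3 and Ccl4, were 9.31 ± 1.60% of young cells and 0.0251 ± 0.0362% of aged cells. The same cluster was 16.01 ± 4.09% of FL-RSV and 12.96 ± 9.22% of ApoE-FL-RSV cells (n = 3 each). Of oral-RSV microglia-like cells 97.3% lay in cluster 11, of few UMIs (median 453), so their shares of other microglia clusters are not comparable and are not given.

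Microglia-like cells of cluster 15, led by Spp1, Lpl, Apoe, Lgals3 and Cst7, were 0.157 ± 0.0214% of young and 0.2504 ± 0.168% of aged cells. They were 3.06 ± 2.42% of FL-RSV cells (1.19–5.79% over libraries) and 4.09 ± 3.39% of ApoE-FL-RSV cells (0.670–7.44%), so both means depend strongly on single libraries. Venous endothelial-like cells of cluster 3, with Vwf, Vcam1, Il1r1 and Lrg1, were 1.79 ± 0.923% of young, 4.40 ± 2.29% of aged, 3.89 ± 0.561% of FL-RSV, 6.56 ± 6.31% of ApoE-FL-RSV and 3.598 ± 2.23% of oral-RSV cells. ApoE-FL-RSV library 3 (13.8%, lowest of that group 2.76%) carries the ApoE-FL-RSV mean. Of oral-RSV endothelial-like cells 72.2% lay in cluster 6, of few UMIs (median 498), so their share of cluster 3 may not be comparable. Border-macrophage-like cells were 2.53 ± 0.332% of ApoE-FL-RSV and 1.61 ± 0.0688% of FL-RSV cells, with no overlap (exact permutation two-sided p = 0.1, the smallest possible; adjusted p = 0.975).

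Immediate early and heat shock genes were lowest in aged libraries, in vessel cells and in microglia-like cells alike. Free RNA from microglia-like cells could carry these transcripts into endothelial-like cells, but the stress genes' ratio of endothelial to microglia level was at least 18.5 times that of microglia markers, which rules this source out. Age of the mice alone could lower them. In endothelial-like cells 9 of 9 treated libraries, labelled with the same age range, lay above the highest aged library. Age as labelled therefore does not account for the gap between treated and aged libraries. Because the treated libraries differ in date and drug, they do not test age for the gap between young and aged ones. Treatment or handling on another batch date does not bear on the gap between young and aged libraries (lowest young 2.04 times the highest aged). Both groups share a labelled batch date and were untreated. There age, or handling within that batch date, stays open as untested. For the gap between treated and aged libraries it could be the source: the lowest treated library had 1.92 times the share of the highest aged one, and this test does not part drug from date. A design with untreated aged mice on the date of the treated ones would part them.

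Genes of oligodendrocytes, microglia and astrocytes were lower in aged endothelial-like cells. Free RNA of other cell types may account for this: 89.5% of 19 measured markers (17) were lower in both endothelial-like and pericyte-like cells, and those cell types were scarcer in aged libraries. A change within endothelial-like cells only is ruled out by the median of −2.15 log2 of the same markers in pericyte-like cells. This does not part free RNA from cells of mixed type left in both classes.

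Age and treatment effects ran opposite across genes. Shared aged libraries could produce this on their own, but with different aged libraries for each effect the correlation nearest 0 was −0.401, so sharing is not the whole cause. The stress response of the cells could drive it. After its slope was removed the correlation nearest 0 was −0.396: over 10399 or 10400 genes FL-RSV went from −0.677 to −0.643, ApoE-FL-RSV from −0.497 to −0.443 and oral-RSV from −0.432 to −0.396. Removing the slope moved each correlation only a little. These fits shared the aged libraries, and sharing alone gave mean correlations of −0.368, −0.299 and −0.157 in the simulations. Values near 0 were therefore out of reach even if stress drove the rest. A single slope may also leave part of a stress response, so this test cannot exclude it. Date or handling of the aged libraries could also drive the opposite movement. In 3 of 3 treatments the correlation lay below the range simulated without effects, which is what this explanation and a drug effect both predict. Endothelial-like cells also lay in different clusters by group, and the correlation was not tested apart from this shift.

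Regrouping the libraries asked whether chance labels reach the same counts. For genes in endothelial-like cells, only the real 1 of 35 groupings reached 3809 for aged against young (highest other 101). The same held for 3621 in FL-RSV against aged (highest other 0), 4221 in ApoE-FL-RSV (3) and 3459 in oral-RSV (9). It also held in pericyte-like cells (936, highest other 40, and 0 among the 7 groupings that part all pairs) and in microglia-like cells (3347, highest other 1). With 35 groupings no result can be rarer than 1 of 35. Every other grouping also mixes the real groups, so a real difference widens its spread and lowers its count. These counts therefore do not exclude chance. For ApoE-FL-RSV against FL-RSV regrouping tests nothing about chance: there are only 10 groupings, and since the real count was 0 any grouping reaches it (10 of 10). The highest other count was 34, with FL-RSV 1, FL-RSV 2 and ApoE-FL-RSV 2 together, which points to structure among the libraries; among the 3 groupings that part the pairs it was 0.

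For gene lists chance is not excluded either. Lists passing camera in endothelial-like cells numbered 12 for aged against young (12 of 35 groupings reached this, highest other 16), 14 for FL-RSV (9 of 35; 19), 16 for ApoE-FL-RSV (8 of 35; 19) and 14 for oral-RSV (13 of 35; 21) against aged. In pericyte-like cells there were 10 (18 of 35; 16, and 12 among groupings that part the pairs) and in microglia-like cells 17 (5 of 35; 20). For ApoE-FL-RSV against FL-RSV the real number was 11 and the highest other 19 (10 among those parting the pairs), reached by 3 of 10 groupings.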
